A study of Homo sapiens with 6 samples.

How the data were processed

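RNA was extracted from 6 samples of MCF-7 cells, 3 with scramble shRNA and 3 with UHRF1 shRNA, with a silica column kit (RNeasy Mini Plus), and libraries were made with a SMARTer mRNA-seq kit, per the labels' protocols. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The aligner, the counter, the annotation and the test that the authors used are not given in the sources used here. GRCh37 is named among the builds in the submitters' processing notes, but the IDs and coordinates of all 2926 genes in the file equal those of GENCODE 29 on GRCh38, so coordinates are given as the file gives them, on GRCh38.

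The only file analysed was the authors' deposited table of the comparison of UHRF1 shRNA with scramble shRNA, with 2926 genes. Per the file headers it holds a mean signal per group, that is gene counts normalized per library and averaged over the group by the authors, a log2 fold change, a p-value and an adjusted p-value. All deposited p-values are under 0.05, so the table is a selection and no number of genes tested is claimed. By the ranks that the adjusted p-values imply, a gene without a row had a p of at least 0.05, was not tested, or lay at the lowest levels, and its level was not analysed here. The deposited log2 fold change had the sign of the difference of the means in all 2926 genes, and among the 2872 genes with a mean of at least 5 it lay within 0.1 of the log2 ratio of the means in 2871. An adjusted p-value of exactly 1 stood in 139 deposited rows, all with a mean of at most 21.3. The symbols of 3 genes had been turned into dates in the deposited table and were restored from their gene IDs.

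Size factors were inferred from the smallest means. Values that 1 read in 1 of 3 libraries would give set the size factor of each library, and all 46 different scramble means and 39 different UHRF1 shRNA means under 5.00 were whole-number combinations of these steps, within the rounding of the table. Higher means cannot be split into libraries, so no counts per library were recovered and no count test was run. The implied size factors were 0.976, 1.02, 1.02 for scramble shRNA and 0.986, 1.01, 1.01 for UHRF1 shRNA. The order of the libraries is unknown.

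Because the table holds group means and the authors' statistics, the design fixed before the data were examined asks for no test of single genes: genes were called at the authors' adjusted p under 0.05 and counted by direction. For each of 34 gene lists, also fixed before the data were examined, the called members that rose or fell were set against all other called genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 29 lists with a called gene. For counts adjusted over the list alone, the Benjamini-Hochberg method was applied to the members' deposited p-values, and members without a row entered with a p of 1, which cannot add a call. Members of families given by name patterns were counted in GENCODE 29. Genes are named by a rule fixed beforehand: UHRF1, UHRF2 and DNMT1, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 over the 2 groups and a gene symbol, and up to 4 called members per list with the largest absolute change at that level. UHRF1, UHRF2 and DNMT1 have no row. The markers of other cell types were among the lists. Alternatives were a threshold of 0.01 or 0.1, a change of at least 2-fold, filters on the mean, all rows and nuclear protein-coding genes.

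In the closing section, the standard error implied by a deposited fold change and p-value was taken from a two-sided normal test, levels per kb used the gene length that the authors' table gives, 3' UTRs came from 1 GENCODE 29 transcript per gene (the principal isoform with the longest coding part), a common shift was tested with Cochran's Q on folds weighted by the implied standard errors, against draws that passed the call, and hexamers were scored in a logistic model of falling with log length, GC content and their squares as covariates. The steps were tested on simulated data. All 3 size factors simulated at the 2926 genes' means were recovered. Tables of simulated p-values with 0, 1 and 5 rows left out were found to miss 0, 1 and 5. Among 1397 genes, all 100 simulated lists of 20 with 90 percent rising were called and 3 of 100 random lists. A hexamer planted in 800 sequences ranked 1. Of 100 simulated sets of 17 genes with 1 common shift 2 were found to differ, and of 100 with differing shifts all 100. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.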

Results

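Gene expression was measured by RNA sequencing in MCF-7 cells, an established human breast cancer cell line per the labels, after infection with lentivirus carrying short hairpin RNAs (shRNAs). The 6 libraries fell into 2 groups of 3, scramble shRNA as the control and shRNA against UHRF1, a protein that binds hemimethylated DNA and is needed to copy DNA methylation after replication. The values analysed were the group means of normalized counts, the log2 fold changes (UHRF1 shRNA over scramble shRNA) and the p-values of the authors' deposited table, which lists 2926 genes that all have an unadjusted p under 0.05. The table holds no value per library, so the spread between replicates enters only through the authors' p-values, and no SD or own test accompanies a gene below. The smallest group means imply size factors between 0.976 and 1.02 for the 6 libraries, so the scaling between libraries was small, and the table gives no read totals from which to compare their depths. Over the listed genes the means summed to 11505568 normalized counts with scramble shRNA and 11367589 with UHRF1 shRNA, which is a part of each library and not its depth.

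The comparison of UHRF1 shRNA with scramble shRNA asks, per the series title, which tumour-related genes depend on DNA methylation controlled by UHRF1. The target gene comes first in a knockdown design. UHRF1 (ENSG00000276043, chromosome 19, 4903080 to 4962154, GRCh38) has no row in the authors' deposited table, nor do its paralogue UHRF2 and the maintenance methyltransferase DNMT1, so their levels were not analysed here. By the ranks that the adjusted p-values imply, UHRF1, if tested, had an authors' p of at least 0.05, unless its mean was at or below about 21.3. A fall of UHRF1 was thus not seen, and the libraries could not be checked against their labels by the target gene. Among other genes of the DNA methylation machinery, the de novo methyltransferase DNMT3B fell to 66.5% of the scramble mean, from 1026 to 682 normalized counts in the authors' deposited table (log2 fold change −0.59, adjusted p = 7.83e-12). Its relative DNMT3A moved the other way, from 181 to 243 normalized counts in the authors' deposited table (log2 fold change 0.42, adjusted p = 0.0348). IDH2, a mitochondrial isocitrate dehydrogenase, rose (log2 fold change 0.38) and AHCY, which clears S-adenosylhomocysteine, fell (log2 fold change −0.24) in the authors' deposited table. Of the 36 genes of this list, 2 rose, 4 fell and 30 did not pass at an adjusted p under 0.05 by the authors' deposited table, and 3 rose and 4 fell when adjusted over the list alone. The list did not pass (adjusted p = 0.835, Fisher's exact test), and it had too few called genes to show that a direction was absent.

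Across the authors' deposited table, 1397 genes passed an adjusted p of 0.05, and these are the genes called below. Of them, 651 rose and 746 fell with UHRF1 shRNA, and 1340 code for proteins. Most changes were small, with a median log2 fold change of 0.28 among the genes that rose and −0.21 among those that fell in the authors' deposited table. With a change of at least 2-fold in addition, 31 genes rose and 14 fell in the authors' deposited table, which turns the balance of directions from 46.6% to 68.9% rising. The median scramble level of all 1397 called genes was 1930 normalized counts in the authors' deposited table. A number alone in parentheses after a gene symbol is that gene's log2 fold change.

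The largest rise among called genes with a symbol and a mean of at least 50 was that of BOLA2B (chromosome 16, 30192934 to 30194306), from 36.2 to 1074 normalized counts in the authors' deposited table (log2 fold change 4.89, adjusted p = 0.00165). This gene has a near-identical copy, BOLA2, with which it can share reads, so its value is uncertain. FABP7, a fatty acid-binding protein of the brain and mammary gland (chromosome 6, 122779475 to 122784074), went from 23.9 to 191 normalized counts in the authors' deposited table (7.97-fold, adjusted p = 3.49e-31). The glycoprotein hormone alpha subunit CGA rose with a log2 fold change of 1.87, FAM124A with 1.62 and the natural killer receptor gene KLRC2, one of a family of similar genes, with 1.49 in the authors' deposited table. NDUFA4L2, a hypoxia-induced mitochondrial protein, followed with a log2 fold change of 1.40 in the authors' deposited table (adjusted p = 0.00519). PPDPFL (adjusted p = 3.44e-14) and the secreted olfactomedin OLFM1 (adjusted p = 6.19e-29) had 1.37 each in the authors' deposited table. SPRY1, an inhibitor of receptor tyrosine kinase signalling, had a log2 fold change of 1.31 and the kinase BRSK2 one of 1.24 in the authors' deposited table.

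The largest falls by the same rule were in FAM167A (log2 fold change −1.13), the interferon-induced GTPase GBP3 (−1.11), the complement regulator C4BPA (−1.10) and the potassium channel KCNJ12 (−1.06) of the authors' deposited table. The pseudogene NMRAL2P fell with a log2 fold change of −0.99, the glycosyltransferases GCNT3 and B3GNT5 with −0.98 and −0.94, and PRG4 with −0.91 in the authors' deposited table. KCNJ12 and NMRAL2P have similar copies elsewhere in the genome and are uncertain for that reason. The cystine transporter SLC7A11 (chromosome 4, 138164097 to 138242349) fell from 771 to 399.9 normalized counts in the authors' deposited table (log2 fold change −0.95, adjusted p = 7.00e-23). OASL, an interferon-induced antiviral protein (chromosome 12, 121019111 to 121039242), fell from 1394 to 729.6 normalized counts in the authors' deposited table (log2 fold change −0.93, adjusted p = 4.39e-36).

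All called genes of the hypoxia and glycolysis list rose. Of the 35 genes of this list, 17 rose, 0 fell and 18 did not pass by the authors' deposited table, and 21 rose and 0 fell when adjusted over the list alone. PFKFB4, which makes the main activator of phosphofructokinase, went from 311 to 536 normalized counts in the authors' deposited table (log2 fold change 0.78, adjusted p = 1.63e-08). The aldolase ALDOC had a log2 fold change of 0.65, the oxygen-sensing prolyl hydroxylase EGLN3 one of 0.55 and the mitophagy receptor BNIP3 one of 0.50 in the authors' deposited table. The list's directions differed from those of the other called genes (adjusted p = 5.97e-05, two-sided Fisher's exact test). The standard errors that the p-values of the authors' deposited table imply for its called members lay at a median percentile of 84 among called genes of similar level. This test and those of the other lists describe the called genes of the authors' deposited table, since genes are not independent replicates and no set test on libraries could be made.

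All called genes in the list of targets of NRF2, the regulator of the oxidative stress response, fell. Of the 30 genes of this list, 0 rose, 14 fell and 16 did not pass by the authors' deposited table, and 0 rose and 15 fell when adjusted over the list alone. Besides SLC7A11, the falls were largest in OSGIN1 (log2 fold change −0.74), the quinone reductase NQO1 (−0.45, from 5632 to 4121 normalized counts) and the export pump ABCC3 (−0.41) of the authors' deposited table. Their directions also differed from those of the other called genes (adjusted p = 0.00241, Fisher's exact test). In the unfolded protein and integrated stress response list, which shares SLC7A11 with it, 2 rose, 7 fell and 22 did not pass of 31 genes by the authors' deposited table, and 3 rose and 7 fell when adjusted over the list alone. The pseudokinase TRIB3 (log2 fold change −0.45) and the stress regulator NUPR1 (−0.31) fell, while the lipoprotein receptor VLDLR rose (0.59) in the authors' deposited table. That list did not pass (adjusted p = 0.494, Fisher's exact test).

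Interferon-stimulated genes fell. Of the 47 genes of the list, 0 rose, 10 fell and 37 did not pass by the authors' deposited table, and 0 rose and 11 fell when adjusted over the list alone. IFI44 (log2 fold change −0.80), IFIT2 (−0.74) and IFIT3 (−0.66), all induced by type I interferon, followed OASL in the authors' deposited table. IFIT2 went from 1809 to 1083 normalized counts in the authors' deposited table (adjusted p = 5.48e-27). The list passed (adjusted p = 0.0167, Fisher's exact test), but not when genes were called at an adjusted p of 0.01 (adjusted p = 0.114, Fisher's exact test). Of 24 antigen presentation genes, 3 rose, 2 fell and 19 did not pass by the authors' deposited table, and 4 rose and 3 fell when adjusted over the list alone. HLA-A (log2 fold change 0.26) and B2M (0.12), which form a class I complex, rose, and the peptidase ERAP1 (−0.18) and the transactivator NLRC5 (−0.16) fell in the authors' deposited table. Of 33 NF-kB and inflammatory genes, 1 rose, 3 fell and 29 did not pass by the authors' deposited table, and 1 rose and 3 fell when adjusted over the list alone. The NF-kB inhibitor TNFAIP3 rose (log2 fold change 0.46), and the superoxide dismutase SOD2 (−0.36) and IER3 (−0.19) fell in the authors' deposited table. Neither list passed (adjusted p = 0.835 for each, Fisher's exact test), and both had too few called genes to show that a direction was absent.

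**Figure D1:**
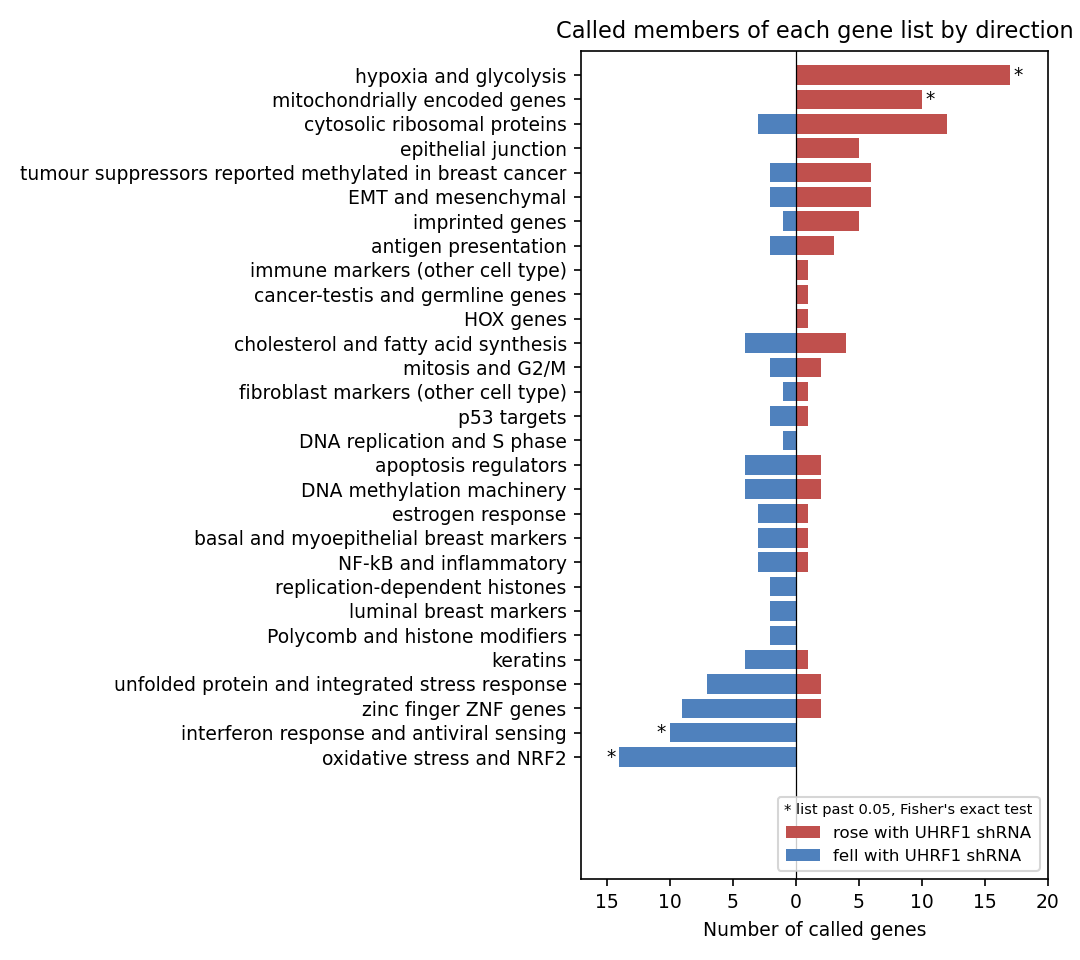
Number of called genes (horizontal axis, genes with an adjusted p under 0.05 in the authors' deposited table) that rose (right of 0) or fell (left of 0) with UHRF1 shRNA, for each of the 29 lists with a called gene. The longest bars are the 17 hypoxia and glycolysis genes that rose and the 14 NRF2 genes that fell, and asterisks mark the 4 lists past 0.05 by Fisher's exact test.

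All called transcripts of the mitochondrial genome rose. Of its 37 genes, 10 rose, 0 fell and 27 did not pass by the authors' deposited table, and 14 rose and 0 fell when adjusted over the list alone. The ribosomal RNA MT-RNR1 had a log2 fold change of 0.38, and the transfer RNAs MT-TI, MT-TY and MT-TL1 had 0.94, 0.43 and 0.40 in the authors' deposited table. The list passed (adjusted p = 0.00450, Fisher's exact test). Transfer RNAs overlap or adjoin longer mitochondrial transcripts and can share their reads, so the members are not separate measurements. The standard errors implied for its called members by the authors' deposited table lay at a median percentile of 92 among called genes of similar level. Of 82 cytosolic ribosomal protein genes, 12 rose, 3 fell and 67 did not pass by the authors' deposited table, and 14 rose and 4 fell when adjusted over the list alone. RPL39 (log2 fold change 0.18) and RPS29 (0.18) rose, and the ribosomal protein-like genes RPS27L (−0.22) and RPL7L1 (−0.18) fell in the authors' deposited table. This list missed the threshold over all lists (adjusted p = 0.0932, Fisher's exact test).

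**Figure D2:**
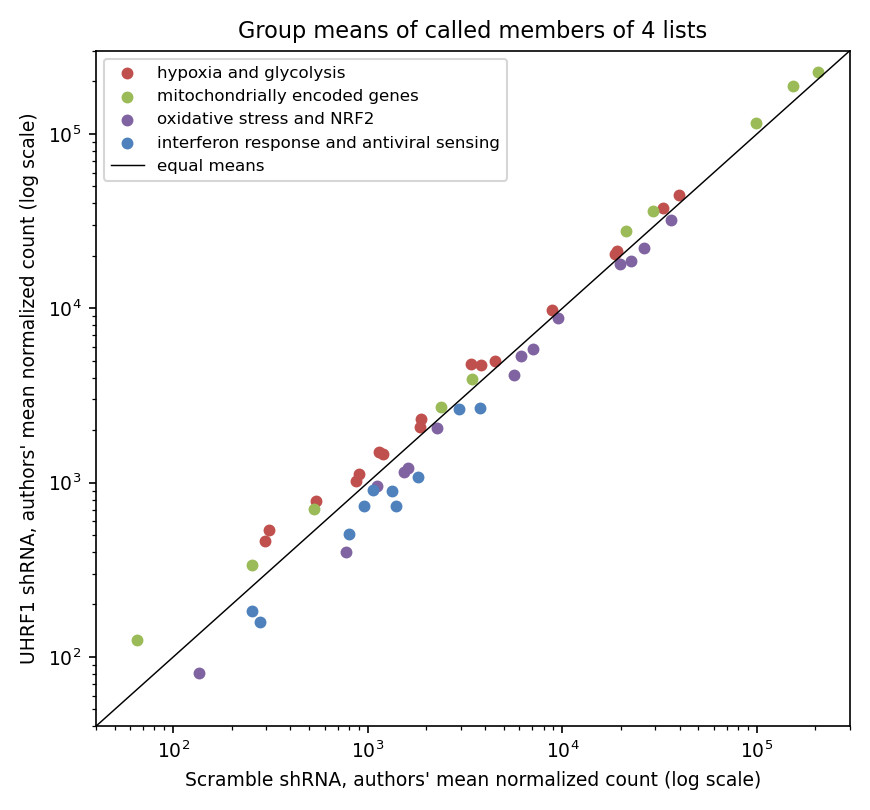
Authors' mean normalized count per gene with scramble shRNA (horizontal, log scale) and with UHRF1 shRNA (vertical, log scale) for the called members of 4 lists, 1 point per gene, with the line of equal means. The 17 hypoxia and glycolysis genes and the 10 mitochondrially encoded genes lie above the line, and the 14 NRF2 genes and the 10 interferon genes below it.

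Markers of breast cell identity were called in both directions. No share called over all tested genes is given here, so these counts do not show that such markers changed less than other genes. The luminal keratins KRT8 (log2 fold change −0.14, 47749 normalized counts with scramble shRNA) and KRT18 (−0.15, 16937) fell in the authors' deposited table, and they were the called genes among 22 luminal markers (0 rose, 2 fell and 20 did not pass, the same counts as when adjusted over the list alone). Some basal markers were abundant in both groups. The basal keratin KRT17 fell from 18981 to 13242 normalized counts in the authors' deposited table (log2 fold change −0.52, adjusted p = 5.70e-42). The smooth muscle kinase MYLK rose (0.74), and the integrin ITGA6 (−0.18) and the laminin chain LAMB3 (−0.15, 5012 normalized counts with scramble shRNA) fell in the authors' deposited table. In all, 1 rose, 3 fell and 18 did not pass of the 22 basal and myoepithelial markers by the authors' deposited table, and 1 rose and 3 fell when adjusted over the list alone. Over the keratin family, 1 rose, 4 fell and 50 did not pass of 55 genes by the authors' deposited table, and 1 rose and 4 fell when adjusted over the list alone, with KRT13 up (0.68) and KRT16 down (−0.49). Of 34 epithelial junction genes, 5 rose, 0 fell and 29 did not pass by the authors' deposited table, and 6 rose and 0 fell when adjusted over the list alone. The called members with the largest changes were the tight junction genes TJP3 (log2 fold change 0.64) and CLDN7 (0.44), the desmosomal PKP2 (0.50) and the epithelial factor ELF3 (0.26) of the authors' deposited table. Of 44 epithelial-mesenchymal transition genes, 6 rose, 2 fell and 36 did not pass by the authors' deposited table, and 6 rose and 3 fell when adjusted over the list alone. The collagen COL3A1 (0.77), the cytokine TGFB1 (0.30) and the lysyl oxidase LOXL2 (0.27) rose and TGFBI (−0.50) fell in the authors' deposited table. The adjusted p of Fisher's exact test was 0.809 for luminal markers, 0.835 for basal markers, 0.809 for keratins, 0.105 for junction genes and 0.452 for transition genes.

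Markers of other cell types were called in the fibroblast and immune lists only. A marker at equal levels in both groups would have no row, so these counts do not show that such cells were absent. Of 12 fibroblast markers, 1 rose, 1 fell and 10 did not pass by the authors' deposited table, and 2 rose and 1 fell when adjusted over the list alone, with COL3A1 up and MFAP5 down (−0.26). Of 16 immune markers, CD19 rose (0.76, from 51.6 to 87.1 normalized counts) in the authors' deposited table, and 1 rose and 0 fell when adjusted over the list alone. No gene of the 10 endothelial markers and of the 16 markers of HEK293 and neural cells was called in the authors' deposited table, also when adjusted over the list alone, and of these SNAP25 had an unadjusted p under 0.05 (log2 fold change 0.21). Fisher's exact test gave an adjusted p of 1 for fibroblast and 0.809 for immune markers.

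The lists of cell division, p53, apoptosis, estrogen response and lipid synthesis did not pass, and the DNA repair list had no called gene to test. Most of them had few called genes, where the test is weak. The epithelial junction list, with 5 rises and 0 falls, had an adjusted p of 0.105 (Fisher's exact test). These results therefore do not show that the lists lacked a direction. Of 46 genes of DNA replication and S phase, the polymerase subunit POLA1 fell (log2 fold change −0.25) and 45 did not pass in the authors' deposited table, the same count as when adjusted over the list alone. Of 42 genes of mitosis, 2 rose, 2 fell and 38 did not pass by the authors' deposited table, and 2 rose and 2 fell when adjusted over the list alone. PTTG1 (0.14) and CDK1 (0.12) rose, and PLK1 (−0.15) and the proliferation marker MKI67 (−0.11) fell, each by under 0.2 on the log2 scale in the authors' deposited table. Of 30 p53 targets, 1 rose, 2 fell and 27 did not pass by the authors' deposited table, and 2 rose and 2 fell when adjusted over the list alone, with DDB2 up (0.19) and RRM2B (−0.23) and AEN (−0.21) down. Of 36 apoptosis regulators, 2 rose, 4 fell and 30 did not pass by the authors' deposited table, and 3 rose and 5 fell when adjusted over the list alone. The pro-apoptotic BMF (0.99) and APAF1 (0.23) rose and the inflammatory caspases CASP1 (−0.69) and CASP4 (−0.38) fell in the authors' deposited table. Of 37 estrogen response genes, 1 rose, 3 fell and 33 did not pass by the authors' deposited table, and 1 rose and 3 fell when adjusted over the list alone. The cadherin CELSR2 rose (0.21), and STC2 (−0.31), cyclin D1 (CCND1, −0.31) and the amino acid transporter SLC7A5 (−0.13) fell in the authors' deposited table. None of 36 DNA repair genes was called in the authors' deposited table, also when adjusted over the list alone, and 5 of them had an unadjusted p under 0.05. Of 33 genes of cholesterol and fatty acid synthesis, 4 rose, 4 fell and 25 did not pass by the authors' deposited table, and 5 rose and 5 fell when adjusted over the list alone, with the kinase PMVK up (0.23) and the desaturase SCD (−0.25), ME1 (−0.23) and DHCR7 (−0.23) down. The adjusted p of Fisher's exact test was 0.835 for apoptosis regulators, 0.835 for the estrogen response and 1 for each of the replication, mitosis, p53 and cholesterol lists.

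Some members were called in gene groups often silenced by DNA methylation. No share called over all tested genes is given here, so these counts do not show that the groups changed less than other genes. Members without a row are counted as not passed, whatever their level. Of 70 tumour suppressors reported methylated in breast cancer, 6 rose, 2 fell and 62 did not pass by the authors' deposited table, and 7 rose and 2 fell when adjusted over the list alone. NDRG2 (log2 fold change 0.70, from 92.2 to 149.7 normalized counts), BNIP3 (0.50) and the phosphatase subunit PPP2R2B (0.31) rose and RASSF5 (−0.32) fell in the authors' deposited table. Of 55 cancer-testis and germline genes, MAGEA1 rose (0.79, from 158 to 273 normalized counts) and 54 did not pass in the authors' deposited table, the same count as when adjusted over the list alone. MAGEA1 belongs to a family of similar genes, and its value is uncertain where reads were split among them. Of 36 imprinted genes, 5 rose, 1 fell and 30 did not pass by the authors' deposited table, and 6 rose and 1 fell when adjusted over the list alone, led by PEG10 (0.37), MEST (0.35), SGCE (0.34) and ZDBF2 (0.27), all of which rose. The adjusted p of Fisher's exact test was 0.452 for tumour suppressors, 0.809 for cancer-testis genes and 0.374 for imprinted genes.

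Chromatin and other gene families completed the lists. Of 35 Polycomb and histone modifiers, 0 rose, 2 fell and 33 did not pass by the authors' deposited table, and 0 rose and 1 fell when adjusted over the list alone, the acetyltransferase CREBBP (log2 fold change −0.22) and the methyltransferase NSD1 (−0.11) being the called genes. Of 71 replication-dependent histone genes, HIST1H2BK (−0.27) and HIST1H1C (−0.21) fell in the authors' deposited table, and 0 rose and 2 fell when adjusted over the list alone. Of 509 ZNF genes, 2 rose, 9 fell and 498 did not pass by the authors' deposited table, and 0 rose and 3 fell when adjusted over the list alone. The called ZNF genes with the largest changes were ZNF704 (−0.47), ZNF618 (−0.40), ZNF706 (−0.37) and ZNF205 (−0.29), which fell in the authors' deposited table. Of 39 HOX genes, HOXC4 rose (0.28) in the authors' deposited table, with 0 called when adjusted over the list alone. None of 53 clustered protocadherin genes and of 9 metallothionein genes was called in the authors' deposited table, also when adjusted over the list alone, and MT2A of the latter had an unadjusted p under 0.05 (log2 fold change −0.13). The adjusted p of Fisher's exact test was 0.295 for ZNF genes and 0.809 for each of the Polycomb, histone and HOX lists.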

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

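Settings with adjusted p under 0.1, all rows and nuclear protein-coding genes were chosen after the data were seen. At an adjusted p under 0.01 the count of called genes was 878 (408 rose, 470 fell), with a change of at least 2-fold 45 (31 rose, 14 fell), and at an unadjusted p under 0.05 2926 (1473 rose, 1453 fell), against 1397 (651 and 746). These counts follow from the thresholds themselves. The filters on the mean, an adjusted p under 0.1 and the restriction to nuclear protein-coding genes left the counts within 1.5 times. With a change of at least 2-fold 1 list had a called gene and 0 lists passed, against 4 lists, while the other settings gave 3 to 5. None of the 6 lists followed (hypoxia, NRF2, mitochondrial, interferon, junction, ribosomal) turned its direction under a setting that gave a value. Of these, only the ribosomal list had called members in both directions. Settings that keep a part of the called genes could not turn the others, so for them this is no check. The filter at a mean of at least 5 removed no called gene (1397 stayed). The interferon list missed the threshold with genes called at 0.01 (adjusted p = 0.114, Fisher's exact test, range over its alternatives 2.12e-04 to 0.114), with 7 genes in place of 10, and the ribosomal list passed when all rows were used (adjusted p = 0.00332, Fisher's exact test).

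No paired analysis was possible because the table holds group means without replicate numbers. For the same reason the planned replicate block, leaving out each replicate, other normalizations, pseudocounts, no filter, and the set tests with preset and estimated correlation were not run, and other splits of the 6 samples were not counted. UHRF1 has no value under any setting. Called genes had a mean of at least 22.2. The 139 rows with an adjusted p of exactly 1 had a mean of at most 21.3, so this floor goes with how the authors' adjustment treated low rows, and an effect of depth on it was not tested.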

Other observations

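All gene groups and tests in this part were chosen after the data were seen, except that the bounds for the matched draws of genes and for the hexamer outside the 3' UTR were set before those values were computed. Cytosolic aminoacyl-tRNA synthetases, which load amino acids onto transfer RNAs, gave 0 rises and 7 falls among 20 genes in the authors' deposited table, led by WARS (log2 fold change −0.27), GARS (−0.25) and CARS (−0.22). Of 28 actin and tubulin cytoskeleton genes, 0 rose and 10 fell in the authors' deposited table, among them TUBB (−0.26), ACTN4 (−0.25) and FLNA (−0.13). Of 34 complement genes, 1 rose and 6 fell in the authors' deposited table: VTN (−0.89), C1S (−0.73), C3 (−0.46), CFB (−0.80), CD55 (−0.20) and C4BPA (−1.10) fell and CLU (0.49) rose. Fisher's exact test gave p = 0.0169, p = 0.00230 and p = 0.130 for these 3 groups, unadjusted and on groups picked for their falls. The lowest adjusted p-values of the authors' deposited table belonged to the growth factor HDGF (−0.70, from 23919 to 14733 normalized counts), the autophagy receptor SQSTM1 (−0.74) and prothymosin PTMA (−0.68), all of which fell.

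Directions were also unevenly spread over the genome. On chromosome 19, 56 called genes rose and 30 fell (adjusted p = 0.00579 over 24 chromosomes, Fisher's exact test). Neighbouring called genes that do not overlap, mitochondrial genes left out, shared their direction in 55.3% of 1342 pairs, against 50.3% (SD 1.36) with directions permuted (p = 1e-04, permutation test, the smallest that 10000 permutations can give). MIR210HG, the host transcript of a hypoxia-induced microRNA and in no list, rose from 125 to 246 normalized counts in the authors' deposited table.

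UHRF1 has no row, and the markers of the line are mixed. The ratios of p to adjusted p in the authors' deposited table give each row a rank, and 0 ranks below the last row lack a gene, which argues against the UHRF1 row having been removed: if UHRF1 was tested, its p was at least 0.05, unless its mean was at or below about 21.3, where rows take no rank. In the scramble means, VIM per kb stood 172 times above the luminal receptor ERBB3, and the basal genes KRT17 (18981 normalized counts), LAMB3 (5012) and SERPINB5 (5681), the kinase AXL (1966) and the urea cycle enzyme CPS1 (79742) were abundant in the authors' deposited table. The luminal keratins KRT8 and KRT18 were abundant as well, at 6939 and 5263 normalized counts per kb. VIM stood at 2431 and KRT17 at 6064. The ratio of VIM to ERBB3 goes with cells other than a luminal line. Of the luminal list only KRT8, KRT18 and ERBB3 have a row, however, so the identity of the line stays open. Fibroblasts as the source of VIM are argued against by DCN, at 0.0520% of VIM per kb, with 16.3 normalized counts, and FAP at 18.9 in the authors' deposited table, although 2 other members of the fibroblast list, COL3A1 (729 normalized counts) and MFAP5 (1171), were not low in the authors' deposited table. Whether the shRNA lowered UHRF1, and whether the labels or the line differ from what was grown, stays open without values per library.

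The joint rise of hypoxia and glycolysis genes may come from the knockdown or from cultures that differed in density or oxygen. Against a bias in length, GC content or level, draws of called genes matched on all 3 gave 6.49 rises of 17 on average (SD 1.94) and at most 14 in 10000 draws, where all 17 members rose. A shift of the scaling, the same for every gene, is argued against as the whole cause by the members' log2 fold changes, which ran from 0.134 to 0.782 in the authors' deposited table and differed by more than their implied standard errors allow (Cochran's Q = 80.6, highest 55.5 in simulated sets of called and risen genes with 1 common shift). A smaller shift in addition stays open. Uneven cultures stay open: the members' implied standard errors had a median percentile of 84 among the 50 called genes nearest in level (permutation p = 0.00120), as would follow if oxygen or density varied between the libraries of a group, while the percentile was 30 for the stress response list (permutation p = 0.161), 55 for the NRF2 genes (permutation p = 0.701), 73 for the interferon genes (permutation p = 0.0686) and 92 for the mitochondrially encoded genes (permutation p = 2.00e-04). A called gene with a larger fold can have a larger implied standard error, and the genes were not matched on fold size. These percentiles therefore do not separate spread between libraries from fold size. The knockdown itself stays among the open explanations and was not tested apart from the others.

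A shRNA can lower other genes through short seed matches in their 3' UTRs, and the hairpin sequences are not known here. Among 4054 hexamers, GGGGCT scored highest for falling (z = 5.50, above all of 1000 simulated outcomes, highest 4.96), with 339 of 705 fallen and 203 of 608 risen genes carrying it, so off-target matches may account for part of the falls. Word biases ran both ways, however: ATATTT scored −4.43, that is for rising. Of the 1000 simulated outcomes, 16 had a lowest score as low (median −3.57). Seed matches of the UHRF1 shRNA do not predict a word for rising, but matches of the scramble shRNA in the control would. ATATTT therefore does not separate seed matches from another bias. Longer words were scored as well while the data were explored, and the simulation does not cover that wider search. In the rest of the same transcripts the score of GGGGCT was −2.90, which argues against a composition trend along whole transcripts, though another property of 3' UTRs stays open. The falls of the NRF2 and interferon genes showed no excess of GGGGCT: 4 of their 24 fallen members (16.7%) carried it, against 6.42 (SD 1.98) among risen genes matched on length and GC content. It was carried by 49% of the 100 fallen genes with the lowest p and by 48.1% of all fallen genes, which include them, and this difference was not tested.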
